A study of Mus musculus with 8 samples.

How the data were processed

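The samples were 8 poly(A)-selected, stranded RNA-seq libraries (TruSeq Stranded mRNA) of mouse hippocampus, 4 from mice given the ATM blocker KU55933 and 4 from mice given vehicle, grouped as the labels state. Every sample is labelled hippocampus, while the extraction text gives RNA input amounts for hypothalamus and PFC, which the sources used here do not resolve. The deposited table held estimated counts (expected counts) per transcript in whole numbers, which the authors made with Salmon 1.4.0, and its column totals differed as in values that were not normalized. Per the labels their processing also used FastQC 0.11.9, DESeq2 1.32.0 and genome build GRCm39. How they were rounded, and any filter on transcripts, were not given in the sources used here. The table listed 74764 transcripts of 19558 genes, with library totals of 34190440 to 46630341 estimated counts. Intervals and floors given for counts cover counting error only.

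Transcript counts were summed per gene. Transcript sequences of GENCODE mouse release 21, used for GC content and length only, matched 99.7% of the transcripts, and 99.82% of all counts fell on matched ones. No coordinates were used, since this release and the authors' build differ. Gene GC content and length were means over the gene's transcripts weighted by abundance. Libraries were compared within groups to look for duplicates, and none were found.

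Genes were filtered with edgeR's filterByExpr and scaled by TMM, which left 15481 genes. KU55933 was compared with vehicle by edgeR's two-sided quasi-likelihood F test with robust dispersion (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. Expression is given as CPM, counts scaled by TMM-adjusted library size, and log2 CPM used a prior count of 2. The same test was run per transcript. Before the data were examined, 50 gene lists were fixed, 21 of them cell type markers. Each was tested with camera at a preset inter-gene correlation of 0.01, with the correlation estimated, and with fry, and adjusted over the 50 lists. Levels of the marker lists, as mean log2 CPM per library, were compared by an exact two-sided permutation test over 70 arrangements, whose smallest p is 0.0286, with adjustment over the 21 lists. Correlation across genes used Spearman's rho.

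The genes named were set by a rule written at the same time. It took Atm, Slc12a5, Grik1 to Grik5, Neto1 and Neto2. It took the 10 largest rises and the 10 largest falls among called genes with a mean of at least 1 log2 CPM and no overlap between groups, leaving out provisional symbols and sex-linked genes. It also took the 4 members with the smallest p of each list that passed camera and up to 4 called members of the chloride transport, AMPA and NMDA, GABA synapse, immediate early and p53 lists. Some genes that met this rule or were counted in a list are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

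Alternatives also fixed beforehand were RLE and upper-quartile scaling, no filter and a filter of 1 CPM in 4 libraries, non-robust dispersion, replicate number as a block, and 1 surrogate variable (sva 3.50.0). Others were DESeq2 1.42.0, limma-voom with and without sample weights, an adjusted p of 0.1, a prior count of 0.5, medians in place of means for marker levels, and each library left out in turn. Added after the data were seen were an offset for each library's spline on GC content (6 degrees of freedom), the same with a spline on length (5 degrees of freedom), the GC slope of each library as a covariate, leaving out KU55933 1 and 2 together, thinning every library to the smallest total, and combinations of these. The comparison was also run on all 35 splits of the 8 libraries into 4 and 4. The tests were tried on simulated counts with known changes. With a linear GC trend of the measured slopes added and no offset, 2597 of 15146 unchanged genes were called. With the offset 16 of 15135 were called, and 82.1% of genes changed 2-fold were recovered. The simulated genes were independent and had no length trend, while the measured GC trend steepens at high GC. The 16 thus does not show how many false calls the offset leaves in these data. Tables were read and drawn with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.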

Results

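Polyadenylated RNA of the hippocampus was sequenced from wild-type C57BL/6 mice at postnatal day 40 that had received KU55933 or vehicle through the nose under anesthesia. KU55933 is a small-molecule blocker of ATM, the kinase that signals DNA double-strand breaks and is lost in ataxia telangiectasia. The vehicle was 4% DMSO in saline, the stated dose was 7.5 mg/kg, and the time from dosing to collection was not given in the sources used here. Each of the 2 groups held 4 libraries, counted in the labels as 4 mice. The 4 vehicle libraries held 40586998 to 46630341 estimated counts and the 4 KU55933 libraries 34190440 to 37499003, so that the vehicle mean was 1.19 times the KU55933 mean. The 13 mitochondrially encoded mRNAs took 4.58% ± 0.168 (SD, n = 4) of the counts in vehicle and 5.27% ± 0.184 (SD, n = 4) in KU55933. As a list they did not pass camera (adjusted p = 0.136, median log2 change 0.19), and with an offset for GC content and length the direction turned (adjusted p = 0.393, median -0.05). The series title concerns the chloride transporter KCC2 and kainate receptors in ATM deficiency, and the comparison of KU55933 with vehicle asks how their mRNAs and the rest of the hippocampal transcriptome differ when ATM is blocked.

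Slc12a5, which encodes the neuronal potassium-chloride cotransporter KCC2, fell in KU55933 from 457 ± 19.5 to 354 ± 19.8 normalised CPM (mean ± SD, n = 4 per group), a 1.29-fold difference. Grik5, which encodes the kainate receptor subunit GluK5, fell 1.98-fold, from 253 ± 27.2 to 128 ± 13.9 CPM. Grik4, which encodes the related high-affinity subunit GluK4, fell 1.35-fold, from 85.0 ± 11.7 to 63.2 ± 3.47 CPM. Neto2, an auxiliary subunit of kainate receptors, rose 1.33-fold, from 50.9 ± 6.86 to 67.9 ± 7.18 CPM. In each of these 4 genes all KU55933 libraries lay on the same side of all vehicle libraries. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 15481 genes, the log2 changes were -0.37 ± 0.07 (SE, adjusted p = 0.00478) for Slc12a5, -0.99 ± 0.10 (adjusted p = 0.000504) for Grik5, -0.43 ± 0.10 (adjusted p = 0.0138) for Grik4 and 0.42 ± 0.11 (adjusted p = 0.0225) for Neto2. The same 4 of the 9 genes passed when adjusted over the list alone, with adjusted p from 8.42e-06 for Grik5 to 0.0063 for Neto2. The kainate receptor genes Grik1, Grik2 and Grik3 and the auxiliary gene Neto1 did not pass the test, with log2 changes of 0.23, 0.16, 0.16 and 0.23 and adjusted p of 0.159, 0.368, 0.324 and 0.126 from edgeR. Atm itself, at 26.0 ± 0.531 CPM in vehicle and 28.5 ± 3.51 CPM in KU55933, did not pass either, with a log2 change of 0.13 ± 0.09 (SE, adjusted p = 0.32 from edgeR). None of these genes passed with a single library left out, but their values moved. Without KU55933 2 the log2 change was 0.06 for both Grik2 and Atm. It was 0.12 for Neto1 without KU55933 1 and 0.26 for Grik3 without vehicle 1. The exonic GC content was 58.1% for Slc12a5, 62.1% for Grik5, 54.1% for Grik4 and 37.3% for Neto2, and fold changes across all genes fell with GC content. With each library's trend on GC content and transcript length taken out as an offset, the log2 changes were 0.09 ± 0.06 for Slc12a5, -0.06 ± 0.08 for Grik5, -0.30 ± 0.10 for Grik4 and 0.20 ± 0.09 (SE) for Neto2. In that edgeR fit 0 of the 9 genes passed, Grik3 and Grik4 had an unadjusted p under 0.05, and the smallest adjusted p over the list alone was 0.0864. Neto2 missed the threshold without vehicle 3 (adjusted p = 0.0716), vehicle 4 (0.0663), KU55933 1 (0.056) or KU55933 2 (0.0632).

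**Figure D1:**
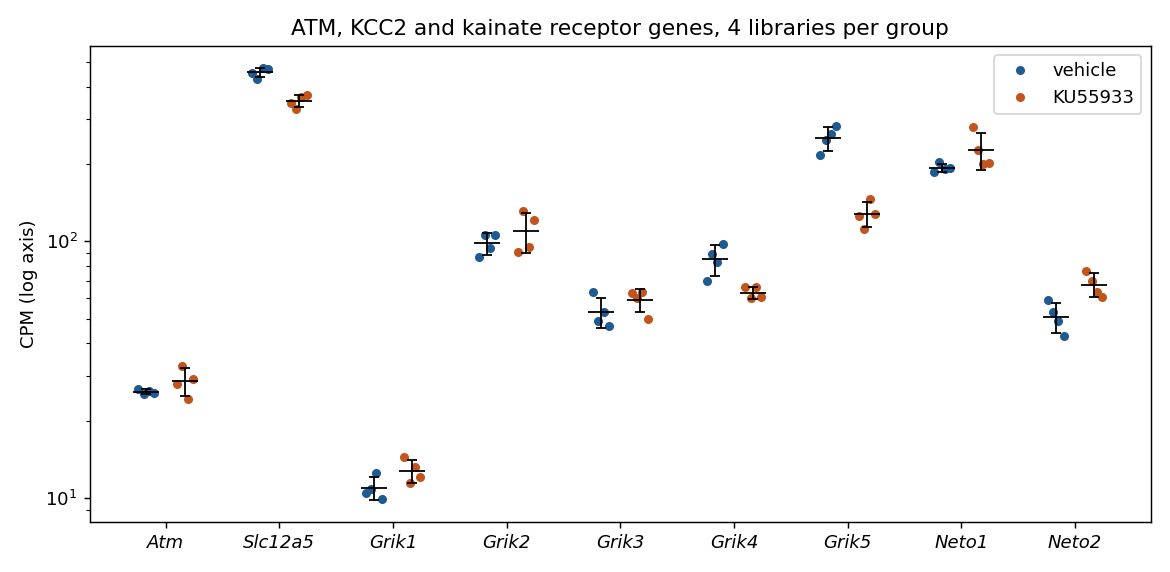
Normalised expression of the title genes in each of the 8 libraries, in CPM on a log axis, with points for single libraries and group means with SD (n = 4 per group). All 4 KU55933 libraries lie below all 4 vehicle libraries for Slc12a5, Grik4 and Grik5 and above them for Neto2, while the groups overlap for Atm, Grik1, Grik2, Grik3 and Neto1.

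The most abundant transcripts of Slc12a5, Grik4 and Grik5 fell. The Slc12a5 transcript ENSMUST00000099092 had a log2 change of -0.38 ± 0.08 (SE, adjusted p = 0.028), and the Grik4 transcript ENSMUST00000034515 one of -0.62 ± 0.12 (adjusted p = 0.0186), by edgeR's quasi-likelihood test per transcript over 45343 transcripts. For Grik5, ENSMUST00000003468 fell by 1.09 ± 0.12 (SE) on the log2 scale (adjusted p = 0.00319) and ENSMUST00000206134 fell by 1.84 ± 0.29 (adjusted p = 0.00942). No transcript of Neto2 passed, the nearest being ENSMUST00000109686 with a log2 change of 0.38 ± 0.11 (adjusted p = 0.0872 from edgeR). The fallen transcripts named had 55.4 to 62.3% GC, and no GC offset was run per transcript. No other transcript of Slc12a5, Grik4 or Grik5 passed. Slc12a5 ENSMUST00000202479 (51.4% GC) had a log2 change of 2.69 and ENSMUST00000137302 (57.5% GC) one of -2.13 (adjusted p = 0.0582 and 0.0813 from edgeR). Grik4 ENSMUST00000114865 (52.2% GC) had -0.21. Grik5 ENSMUST00000206132 (54.7% GC) had 0.92 and ENSMUST00000205328 (62.2% GC) -0.50. The counts per isoform are estimates whose assignment uncertainty is not used here.

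Across the transcriptome, 3338 of 15481 tested genes differed in KU55933, 1071 higher and 2267 lower. The largest falls among genes whose groups did not overlap were those of Fam177a, Prr7, Pcsk1n and C1qtnf4. Pcsk1n, which encodes the proSAAS inhibitor of prohormone convertase, fell from 167 ± 121 to 9.98 ± 3.98 CPM (SD, n = 4 per group), with 67.9 and 55.5 CPM in vehicle 1 and 2 and 270 and 273 CPM in vehicle 3 and 4. Prr7, a postsynaptic density protein gene of 69% GC, fell from 19.6 ± 13.5 to 1.11 ± 0.339 CPM, and C1qtnf4, a secreted C1q-family protein gene of 70.7% GC, from 42.9 ± 28.6 to 2.77 ± 1.30 CPM. Fam177a had 25.1 ± 18.9 CPM in vehicle and 0.993 ± 1.41 CPM in KU55933, while the closely named gene Fam177a2, chosen after its values were seen, had 14.95 ± 17.7 and 43.2 ± 0.886 CPM (adjusted p = 0.453 from edgeR). Whether counts moved between these 2 genes was not tested, so the fall of Fam177a need not be one of expression. Smaller falls were those of the tubulin polyglutamylase subunit gene Tpgs1 (log2 change -2.44 ± 0.33 SE) and the transcription factor gene Cebpd (-2.42 ± 0.43). They also included the linker histone gene H1f10 (-2.42 ± 0.33), the zinc finger genes Zfp771 (-2.30 ± 0.45) and Znrd2 (-2.15 ± 0.21), and the AP-1 gene Junb (-2.18 ± 0.31). In all of these fallen genes vehicle 1 and 2 lay below vehicle 3 and 4, for Prr7 at 7.77 and 8.28 against 28.4 and 33.9 CPM. The labels name no batch, and whether these vehicle libraries differed in preparation was not tested. The largest rises included the ribosomal protein pseudogenes Rps7-ps3, from 2.27 ± 0.373 to 24.2 ± 10.5 CPM, Rpl14-ps1, from 10.6 ± 1.08 to 26.1 ± 5.86 CPM, and Rpl15-ps3, from 8.53 ± 2.16 to 22.5 ± 9.16 CPM. Rps13-ps2, chosen after its values were seen, had 0 counts in every vehicle library and 16.8 ± 4.42 CPM in KU55933, at least 235-fold higher than a floor of 3 counts per library. Whether counts moved between single pseudogenes and ribosomal protein genes was not tested, so these rises need not be ones of expression. Slc17a6, the vesicular glutamate transporter gene of thalamic and other subcortical neurons, rose from 7.12 ± 2.71 to 17.3 ± 3.94 CPM. Further rises were those of the synaptotagmin gene Syt9 (1.29 ± 0.40), the estrogen receptor gene Esr1 (1.20 ± 0.31), AW551984 (1.07 ± 0.22), the glycine receptor gene Glra3 (1.04 ± 0.29) and the cGMP-dependent kinase gene Prkg2 (1.01 ± 0.20). The adjusted p of these genes of the naming rule lay between 0.000504 for Znrd2 and 0.0495 for Syt9, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Leaving out single libraries ended the calls of Syt9 (adjusted p up to 0.136, all 4 vehicle libraries and KU55933 1 and 2) and Esr1 (up to 0.079, vehicle 2, 3 and 4 and KU55933 2). The same held for Glra3 (up to 0.0946, vehicle 2, 3 and 4 and KU55933 1 and 2), Fam177a (up to 0.0978, vehicle 2, 3 and 4 and KU55933 2 and 3) and Rpl15-ps3 (0.0608, vehicle 3). Syt9 had a log2 change of 0.77 without KU55933 1.

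Genes rich in GC were lower and genes poor in GC higher in KU55933. Among the 1547 genes of 31.9 to 41.9% GC, which include Neto2, Grik2 and Neto1, the median log2 change was 0.24 and 26.3% were called higher. Among the 1547 genes of 58 to 71.3% GC, which include Slc12a5, Grik5 and Dlgap3, the median was -0.66 and 74.1% were called lower. Across 15470 genes, which are not independent replicates, Spearman's rho of the log2 change with GC content was -0.71. The slope of expression on GC content, in log2 per 10 percentage points, was 0.21 ± 0.06 in vehicle and -0.21 ± 0.12 in KU55933 (SD, n = 4), without overlap (exact two-sided permutation p = 0.0286, the smallest that 70 arrangements allow). It was -0.275 and -0.344 in KU55933 1 and 2, which also had high choroid plexus markers, and -0.115 and -0.119 in KU55933 3 and 4. In vehicle 1 and 2 it was 0.134 and 0.193, and in vehicle 3 and 4 0.269 and 0.256. With the GC and length offset, edgeR called 309 genes, 107 higher and 202 lower, of which 214 were also called in the same direction without it and 32 in the opposite one. Rps7-ps3 (offset log2 change 3.35 ± 0.36), Pcsk1n (-3.64 ± 0.63), Cebpd (-2.41 ± 0.43), Prr7 (-1.97 ± 0.27), C1qtnf4 (-1.52 ± 0.25), Znrd2 (-1.43 ± 0.14), Rpl14-ps1 (1.35 ± 0.16) and Junb (-1.16 ± 0.22) passed in both fits, as did Tpgs1, AW551984 and Prkg2. H1f10 (-0.07 ± 0.18) and Zfp771 (-0.41 ± 0.22) did not pass with the offset, nor did Fam177a, Slc17a6, Rpl15-ps3, Esr1, Syt9 and Glra3, with adjusted p of 0.0947, 0.0633, 0.0674, 0.122, 0.177 and 0.18. In that fit the log2 changes were -4.89 for Fam177a, 1.08 for Slc17a6, 1.51 for Rpl15-ps3, 1.25 for Syt9 and 0.79 for Glra3. The 2 groups did not overlap in 4127 genes, 26.7% of those tested against 2.86% by chance. The higher count was 1790 without vehicle 1 and fell to 188, 151 and 165 without vehicle 2, 3 or 4 and to 552, 401 and 670 without KU55933 1, 2 or 3. The lower count was 1446 without vehicle 3, and the total was 1809, 1597 and 1737 without vehicle 2, 3 or 4 and 2004 without KU55933 2. With the offset the total was 746 without vehicle 1, 162, 85 and 93 without vehicle 2, 3 or 4, and 189, 78 and 134 without KU55933 1, 2 or 3.

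**Figure D2:**
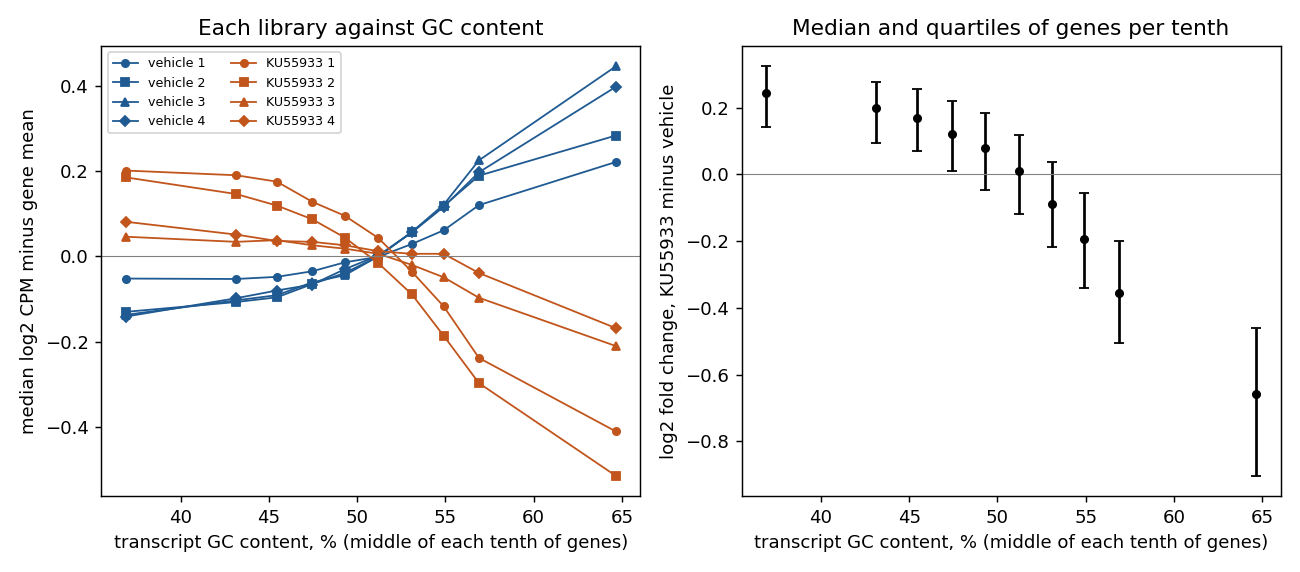
Change in expression by GC content, in log2 units against percent GC of the transcripts, for 10 equal bins of the tested genes, with medians of single libraries on the left and the median fold change with quartiles on the right. The median log2 change runs from 0.24 in the bin poorest in GC to -0.66 in the richest, and the trends of the 4 vehicle and the 4 KU55933 libraries run in opposite directions.

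Genes of the excitatory postsynaptic scaffold, the proteins that hold glutamate receptors at the synapse, were lower as a group. Of 26 measured members 12 fell, 2 rose and 12 did not pass, against 15 lower and 3 higher adjusted over the list alone, with a median log2 change of -0.25. Dlgap3, a binding partner of PSD-95, fell 2.70-fold from 246 ± 43.5 to 90.9 ± 21.1 CPM (SD, n = 4 per group), and the exchange factor gene Psd 2.24-fold from 533 ± 77.4 to 238 ± 33.8 CPM. Iqsec2 fell 1.51-fold and Dlgap4 1.49-fold, while Homer1 and Dlg1, chosen after their values were seen, rose with log2 changes of 0.56 and 0.30. Both rises ended without vehicle 2, 3 or 4 or KU55933 2 or 3, where edgeR called 0 members higher, and without KU55933 1 it called 1 higher. The list passed camera with a preset correlation (adjusted p = 0.000133 over 50 lists), with adjusted p = 0.977 with an estimated correlation. The median GC content of the list was 55.2%, against 38.6% for Homer1 and 45.3% for Dlg1. Under the GC and length offset the median log2 change was -0.07 and camera's adjusted p was 0.211. EdgeR then called 0 of the 26 genes, and Psd had a log2 change of -0.22 ± 0.07 (SE).

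Among ionotropic glutamate receptors of the AMPA and NMDA types, 6 of 23 measured genes fell, 1 rose and 16 did not pass (6 lower and 2 higher adjusted over the list alone). The obligatory NMDA receptor subunit gene Grin1 fell 1.52-fold from 520 ± 34.9 to 342 ± 37.7 CPM, and the AMPA receptor auxiliary genes Cnih2 and Cacng8 fell 1.73-fold and 2.01-fold (mean ± SD, n = 4 per group). Grin2c fell 1.62-fold, and Gria4, an AMPA subunit gene chosen after its values were seen, rose with a log2 change of 0.33. The list did not pass camera (adjusted p = 0.701, median log2 change -0.05). Under the GC and length offset it passed in the other direction (adjusted p = 0.0186, median 0.10), with adjusted p = 0.949 with an estimated correlation. Without vehicle 2 or 4, 0 genes of the list were higher by edgeR, so the call of Gria4 ended. These 4 fallen genes had 59.1 to 66.1% GC, and with the GC and length offset Cacng8 was higher in KU55933 by edgeR, with a log2 change of 0.52 ± 0.08 (SE, adjusted p = 0.0102). Grin2d, chosen after its values were seen, was higher too, with 0.69 ± 0.14 (adjusted p = 0.041). The offset log2 changes of Grin1, Cnih2 and Grin2c were -0.03, 0.20 and 0.13, none of them past the threshold.

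In the cation-chloride cotransport list, 4 of 15 measured genes fell, 2 rose and 9 did not pass (5 lower and 2 higher adjusted over the list alone). Beside Slc12a5, the kinase gene Wnk2, which acts upstream of these transporters, fell from 111 ± 7.33 to 69.1 ± 6.84 CPM (SD, n = 4 per group). The KCC1 gene Slc12a4 fell from 22.8 ± 0.840 to 15.6 ± 0.972 CPM, and Slc12a9 from 34.4 ± 4.84 to 18.3 ± 3.94 CPM. The kinase genes Stk39 and Wnk3, chosen after their values were seen, rose with log2 changes of 0.39 and 0.34. EdgeR called 0 genes of the list higher without vehicle 2, 3 or 4 or KU55933 1 or 2, 1 without KU55933 3 and 4 without vehicle 1. Camera's adjusted p was 0.604, while fry passed the list as lower (adjusted p = 0.0453). With the GC and length offset fry did not pass it (adjusted p = 0.749). The 4 fallen genes had 57.2 to 60.4% GC, and with the GC and length offset edgeR called 0 of the 15, Slc12a9 alone having an unadjusted p under 0.05 among the fallen ones (log2 change -0.28 ± 0.11 SE).

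In the GABA synapse list, 4 of 24 measured genes rose, 2 fell and 18 did not pass (9 higher and 4 lower adjusted over the list alone). The receptor subunit genes Gabrg1 and Gabrg3 rose 1.47-fold and 1.26-fold, as did Gabra3 and Gabrb1, chosen after their values were seen, with log2 changes of 0.77 and 0.27. Slc32a1, which encodes the vesicular GABA transporter, fell 1.63-fold from 47.8 ± 6.53 to 29.4 ± 4.10 CPM, and Nlgn2, the adhesion protein of inhibitory synapses, fell by 0.40 on the log2 scale (CPM as mean ± SD, n = 4 per group). Camera's adjusted p was 0.181. The rises numbered 8 without vehicle 1 and 7 without KU55933 4, but 0 without vehicle 2 or KU55933 1 or 2 and 1 without vehicle 3 or 4 or KU55933 3. Gabrg1 and Gabrg3 had 35% and 43% GC and the fallen Slc32a1 and Nlgn2 61.9% and 59.6%. With the GC and length offset edgeR called 0 of the 24, and Slc32a1 and Nlgn2 had log2 changes of 0.21 and 0.22. Leaving out vehicle 2 or 4 or KU55933 1, 2 or 3 ended the calls of both Gabrg1 and Gabrg3 and leaving out vehicle 3 that of Gabrg1 (adjusted p up to 0.0968 for Gabrg1 and 0.0993 for Gabrg3).

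Immediate early genes, which neurons switch on with activity, were lower where they passed the test, apart from Inhba. Of 31 measured genes 9 fell, 1 rose and 21 did not pass, the same counts as adjusted over the list alone. Junb fell 4.52-fold from 27.8 ± 8.97 to 6.15 ± 2.08 CPM, Ier2 3.32-fold, Gadd45g 2.47-fold and Jun 1.74-fold from 98.5 ± 18.6 to 56.7 ± 4.99 CPM (SD, n = 4 per group). Inhba, an activin subunit gene chosen after its values were seen, rose with a log2 change of 0.68. Camera's adjusted p for the list was 0.113, but 0.000156 without vehicle 2, 0.0413 without KU55933 3 and 0.664 without vehicle 1 (median log2 change -0.09, against -0.23 with all libraries), all with the preset correlation, and 0.977 with all libraries and an estimated correlation. The median GC content was 55%, and without vehicle 1 edgeR called 4 higher. EdgeR with the GC and length offset called Junb alone (log2 change -1.16 ± 0.22 SE, adjusted p = 0.0412), and the log2 changes of Gadd45g, Ier2 and Jun were -0.62, -0.92 and -0.55 (adjusted p = 0.0514, 0.0682 and 0.0607).

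Targets of p53, a transcription factor that ATM activates after DNA damage, were called in both directions at about the rate of all genes. Of 27 measured genes 4 fell, 2 rose and 21 did not pass (5 lower and 4 higher adjusted over the list alone). Over all 15481 tested genes 21.6% were called, 2267 lower and 1071 higher, so these counts do not set the list apart. The rises numbered 6 without vehicle 1, 4 without KU55933 4, 0 without vehicle 2 or 3 and 1 without vehicle 4 or KU55933 2 or 3. The pro-apoptotic gene Bbc3 fell 3.63-fold from 6.26 ± 2.18 to 1.72 ± 0.443 CPM, Dcxr 1.86-fold and the stress gene Sesn2 1.26-fold, while the death receptor gene Fas rose 1.90-fold from 0.995 ± 0.181 to 1.89 ± 0.520 CPM (SD, n = 4 per group). Bax fell and the DNA polymerase gene Polk rose, both chosen after their values were seen, with log2 changes of -0.41 and 0.34. The list did not pass camera (adjusted p = 0.826), its median log2 change being 0.10 and its mean -0.03. The GC content was 65.4% for Bbc3 and 43.5% for Fas, and with the GC and length offset their log2 changes were -0.41 and 0.78, neither past the threshold. Sesn2 turned to 0.20 and Dcxr had -0.17, neither of them called. In that fit edgeR called 1 target higher, Phlda3, chosen after its values were seen (log2 change 0.58 ± 0.12 SE, adjusted p = 0.0447, against -0.41 without the offset), and 0 lower. The call of Fas ended without vehicle 2 (adjusted p = 0.0683), vehicle 3 (0.0672) or KU55933 3 (0.0569). Of 37 DNA damage response and repair genes 3 fell, among them Xrcc1 and H2ax, and 2 rose (Xrcc2 and Nbn), the named ones chosen after their values were seen. The share called was below that of all tested genes. Adjusted over the list alone 1 was lower and 0 higher. The rises numbered 0 without vehicle 2, 3 or 4 or KU55933 1, 1 without KU55933 2 or 3 and 4 without vehicle 1, and the falls 2 without vehicle 2 and 1 without vehicle 3 or 4 or KU55933 1, 2 or 3. Camera's adjusted p was 0.626, and with the GC and length offset edgeR called 0 of the 37. Of the 6 genes of ATM and related kinases edgeR called 0, and camera's adjusted p was 0.826.

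Cytosolic ribosomal protein genes, which encode the protein part of the ribosome, were lower as a group. Of 79 measured members 30 fell, 6 rose and 43 did not pass (31 lower and 12 higher adjusted over the list alone), with a median log2 change of -0.17. EdgeR called 18 lower without vehicle 3 and 19 without vehicle 4, and the rises numbered 1, 1 and 2 without vehicle 2, 3 or 4 and 3 without KU55933 1 or 3. The median was -0.08 without KU55933 2 and -0.09 with the GC and length offset. Rpl36 fell 4.01-fold from 52.0 ± 5.70 to 12.97 ± 3.55 CPM, Rps4l 3.46-fold, Rplp2 2.58-fold from 85.3 ± 10.6 to 33.1 ± 5.99 CPM and Rpl10a 1.58-fold (SD, n = 4 per group). The list passed camera (adjusted p = 0.00307), with adjusted p = 0.977 with an estimated correlation, and did not pass fry (adjusted p = 0.31). Its median GC content was 51.5%, and with the GC and length offset edgeR called 12 members lower and 0 higher, all 12 lower without the offset too, among them Rpl36 (log2 change -1.33 ± 0.11 SE, adjusted p = 0.000886), Rplp2 (-1.17 ± 0.12, 0.00151), Rps4l (-1.21 ± 0.12, 0.00151) and Rpl10a (-0.45 ± 0.06, 0.00809). In that fit camera's adjusted p was 2.71e-09, with adjusted p = 0.949 with an estimated correlation.

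Choroid plexus markers, genes of the epithelium that makes cerebrospinal fluid, were high in 2 of the 4 KU55933 libraries. Their mean was 4.20 and 3.96 log2 CPM in KU55933 1 and 2, 1.42 and 1.30 in KU55933 3 and 4, and 1.19 to 1.85 in vehicle, and the groups overlapped (exact two-sided permutation p = 0.2). Kcnj13, a potassium channel of that epithelium, rose from 0.624 ± 0.310 to 6.11 ± 5.94 CPM and Cab39l from 26.4 ± 1.99 to 37.0 ± 8.93 CPM, and the other 17 of the 19 measured members did not pass (mean ± SD, n = 4 per group). Among these were Folr1 and Prlr, which passed without KU55933 3 or 4 (adjusted p = 0.0225 to 0.0289), and Ttr, chosen after its values were seen, with 50.4 ± 22.6 and 565 ± 609 CPM. Adjusted over the list alone 0 were called by edgeR, while adjusted over all genes 10 and 15 members rose without KU55933 3 or 4. The list passed camera (adjusted p = 0.00162), with adjusted p = 0.977 with an estimated correlation, and its median log2 change was 1.91. The median was 1.21 without KU55933 1. Without KU55933 1 and 2 it was -0.12 and camera's adjusted p 0.983. Under the GC and length offset camera passed too (adjusted p = 1.24e-05, median 1.74, adjusted p = 0.949 with an estimated correlation), but edgeR called 0 members, with log2 changes of 3.16 ± 0.96 (SE, adjusted p = 0.163) for Kcnj13, against 3.28 ± 0.98, and 0.30 ± 0.14 (adjusted p = 0.34) for Cab39l, against 0.48 ± 0.15. The calls of Kcnj13 and Cab39l ended without either of these libraries or without vehicle 2, 3 or 4 (adjusted p up to 0.139 and 0.121), that of Kcnj13 also without vehicle 1 (0.0801).

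Over the 21 marker lists of hippocampal, vascular and neighboring cell types the smallest exact two-sided permutation p was 0.0571. With 0.0286 as the smallest p that 70 arrangements allow, a change in a few lists could not pass after adjustment over 21. Thalamic neuron markers lay at 2.94 ± 0.13 log2 CPM in vehicle and 3.32 ± 0.35 in KU55933 (SD, n = 4; exact two-sided permutation p = 0.0571, adjusted p = 0.3997), and 2 of their 11 genes, Slc17a6 and Tcf7l2, rose, the last chosen after its values were seen. Of these only 1 rose without vehicle 2, 3 or 4 or KU55933 1 or 4, and 4 genes of the list rose without KU55933 3. For the list, camera's adjusted p was 0.0835 (median log2 change 0.35) and 0.00959 with the GC and length offset (median 0.40), where edgeR called 0 of its genes and adjusted p was 0.949 with an estimated correlation. Without the offset it was 0.0336 and 0.00599 without vehicle 1 or KU55933 3, but 0.378 without KU55933 4 (median 0.19), the library with the highest mean of these markers (3.73 log2 CPM). Dentate granule neuron markers lay at 6.36 ± 0.28 and 6.02 ± 0.16 log2 CPM, and CA1 pyramidal neuron markers at 5.50 ± 0.36 and 5.40 ± 0.16. Oligodendrocyte markers ranged from 6.23 to 7.34 log2 CPM within vehicle, and astrocyte and microglia markers differed between the group means by 0.03 and -0.10 log2 CPM.

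**Figure D3:**
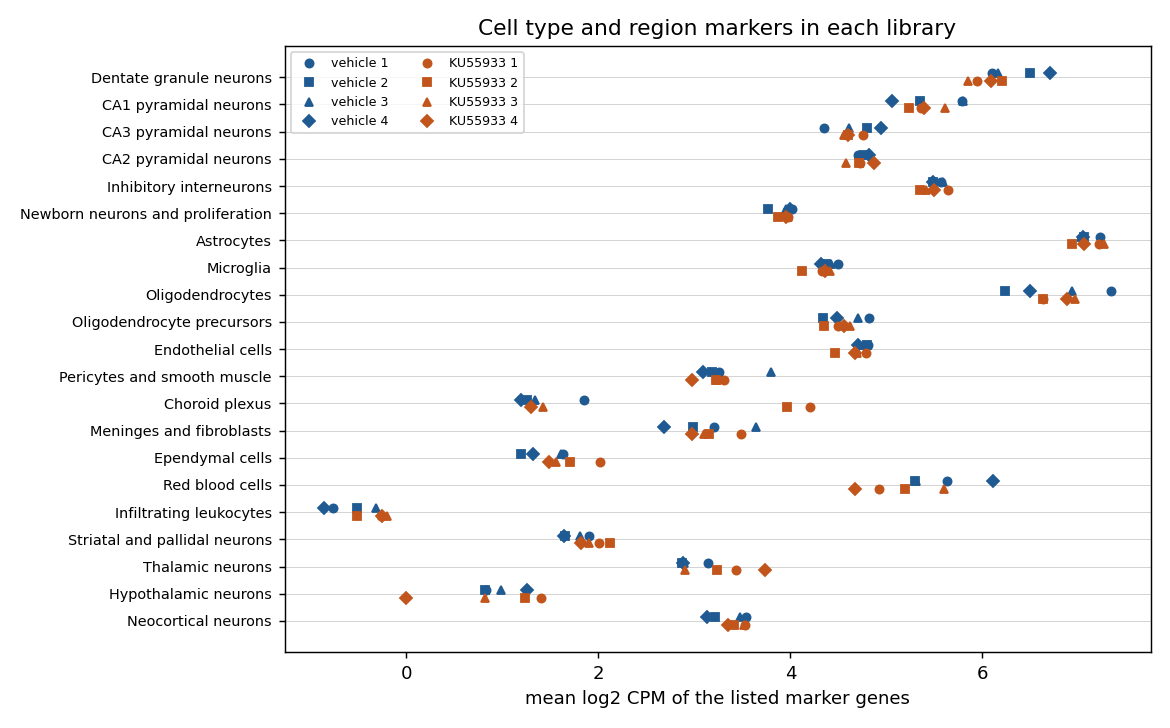
Mean expression of cell type marker lists in each library, in log2 CPM, with vehicle and KU55933 libraries shown apart. KU55933 1 and 2 lie at 4.20 and 3.96 for choroid plexus, above the other 6 libraries, and the groups overlap in each of the 21 lists.

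Without KU55933 1 and 2, in 6 libraries, edgeR called 1090 genes, 105 higher and 985 lower. Calls that ended with little change in the log2 change included those of Grik4 (-0.42, adjusted p = 0.0972), Pcsk1n (-3.83, 0.0715), C1qtnf4 (-3.50, 0.054), Prr7 (-4.00, 0.0501), Cebpd (-2.19, 0.0784), Zfp771 (-2.16, 0.115), Dcxr (-0.87, 0.0661) and Sesn2 (-0.29, 0.0772). The calls of Slc17a6 (1.01, adjusted p = 0.102), Prkg2 (0.80, 0.0805), Neto2 (0.29, 0.182), Grin2c (-0.50, 0.0708), Gabrg1 (0.42, 0.203) and Gabrg3 (0.27, 0.193) ended with somewhat smaller values. Those of AW551984 (0.67, 0.0729), Rpl15-ps3 (0.92, 0.132), Syt9 (0.52, 0.232), Esr1 (0.47, 0.142) and Glra3 (0.38, 0.219) ended with log2 changes more than 1.5 times smaller.

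Single transcripts differed in both directions, with more falls than rises. Of 45343 transcripts tested 3065 differed, 480 higher and 2585 lower, in 2358 genes, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In 119 genes, 126 transcripts had 0 counts in every library of one group and 20 or more in every library of the other, 90 of them at 0 in KU55933 and 36 at 0 in vehicle. The synaptic vesicle gene Syngr3 had such a transcript, at 2145 to 3007 counts in KU55933, as did the peroxiredoxin gene Prdx2, at 1578 to 1890 counts. The scaffold gene Psd had one at 859 to 1154 counts in KU55933 and another, at 0 in KU55933, with 2042 to 2410 counts in vehicle. The dynactin gene Dctn1 had one at 0 in KU55933 with 3276 to 3971 counts in vehicle, and the neuronal gene Sez6 one with 1516 to 3262. These genes were chosen after their values were seen. The median GC content was 57.5% for those at 0 in KU55933 and 53.6% for those at 0 in vehicle. The transcript count was 1446 without vehicle 3, 1660 without vehicle 4, 1737 without KU55933 1 and 1454 without KU55933 2.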

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

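The comparison of GC slopes within and between groups, and the split count for transcripts at 0 in 1 group, were tests chosen only after the result was seen, as was the GC and length offset.

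Of 176 groups of 4 values examined, 6 held a library whose gap to its neighbor took up most of the group's range by Dixon's ratio, and chance gives about 1 in 20. Vehicle 1 had a total of 46.63 M counts, against 40.59 M to 40.87 M in the other vehicle libraries. KU55933 1 had 59385 transcripts above 0, against 61619 to 61974. Astrocyte markers in vehicle 1 lay at 7.22 log2 CPM, against 7.03 to 7.06, and thalamic neuron markers in vehicle 1 at 3.14, against 2.87 to 2.89. Zfp771 had 3.41 CPM in KU55933 3, against 2.31 to 2.42, and Ier2 had 2.77 CPM in vehicle 2, against 5.11 to 5.54.

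The real grouping was compared with all 35 splits of the 8 libraries into 4 and 4. For genes called by edgeR, only 1 of 35 splits, the real one, gave as many as 3338, and the highest other gave 1. The same held for 1071 higher (1 of 35, highest other 1) and 2267 lower genes (1 of 35, highest other 1). Since 1 of 35 is the least that these splits allow, chance is made unlikely for these counts but is not excluded. Every other split mixes libraries of the 2 groups, so a difference between the groups widens the spread within it and lowers its count. With the GC and length offset 1 of 35 splits gave as many as 309 genes, the highest other giving 6. For transcripts 1 of 35 gave as many as 3065, the highest other giving 2. For lists passing camera all 35 splits gave as many as 3, the highest other giving 20 and the lowest 3, so chance cannot be excluded for the number of lists. Whether the larger numbers come from a structure of the samples or from the preset correlation was not tested in the other splits. In the real grouping the 3 lists that passed had estimated correlations above the preset 0.01. These were 0.928 for choroid plexus, 0.471 for ribosomal proteins and 0.151 for the scaffold. Other lists had lower ones, such as -0.049 for the title genes. With an estimated correlation the real grouping passed 0 lists. Simulated counts with the measured GC trend and no list shifted passed 2 lists, or 3 with the offset.

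The fall of log2 changes with GC content runs through the title genes and the postsynaptic scaffold. With every library thinned to the smallest total, Spearman's rho across genes was -0.71, the value without thinning. The trend thus did not need unequal totals in the calculation. Thinning keeps each gene's expected share of its library, so rho was bound to change little. It cannot exclude a difference in preparation or sequencing that goes with depth. A GC-dependent bias in single libraries may account for the fall with GC content. Within genes the GC-richer of the 2 most abundant isoforms had the lower fold change more often, as such a bias would give. Spearman's rho was -0.36 over 10060 pairs (95% bootstrap interval -0.38 to -0.34). That interval resamples pairs from the same libraries and leaves out the spread between mice. An effect of KU55933 on GC-rich genes cannot be told apart from it by the slopes, because they separate the groups without overlap while the larger range within a group, 0.229 log2 per 10 points among KU55933 libraries, was 53.7% of the gap between the group means. Library preparation and treatment may have gone together, and the labels name no batch.

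Under the GC and length offset 12 of 79 ribosomal protein genes were called lower, against 30 without it, the median log2 change was -0.09 against -0.17, and camera did not pass with an estimated correlation in either fit (adjusted p = 0.949 and 0.977). Movement of their reads to processed pseudogenes such as Rps7-ps3 and Rps13-ps2 is argued against as the whole cause, since 424 pseudogenes gained 186 CPM in all while the 79 ribosomal protein genes lost a net amount (-1148.6 CPM), a ratio of 0.162. The median log2 change was -0.165, against -0.002 in genes matched on GC content and length, which hardly fell. The difference of -0.163 (95% bootstrap interval over genes -0.30 to -0.11) lay between the bounds set for and against. That interval leaves out the spread between mice. A part played by GC content stays open, since the GC offset alone brought the median to -0.06. With length added it was -0.09, so the offsets do not show a part played by short length. A lowering of ribosomal protein mRNA by KU55933 also stays open. After the offset 29.1% of members (23 of 79) were lower without overlap and 7 were higher. The 29.1% fell short of the share set before this test was run, though after the data were seen. For a single gene chance gives 1.43% in each direction. Members moved together (estimated inter-gene correlation 0.364 in that fit), so their number cannot be set against that chance share. These explanations cannot be told apart, because the difference from matched genes falls between those bounds and any difference between library preparations goes with the treatment.

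In 119 genes, among them Syngr3 and Prdx2, 126 transcripts were at 0 in every library of 1 group and at 20 or more in every library of the other, and 1 of 35 splits, the real one, gave as many (highest other 14). Counts moving between isoforms may explain most, since the genes' summed counts hardly differed after the offset (median absolute log2 change 0.102, over 1 in 4 of 119 genes), and isoforms too alike to tell apart may be where they move, since a median 0.7% of their 31-base words was their own, 0.075 of the share in matched transcripts. A GC-dependent bias is in line with the GC content of those lost in KU55933, 3.85 percentage points above that of those gained. Of 8363 isoforms with most of their words unique 0 were all-or-none, against 121 of 31911 others, a ratio of 0. This met the bound, set before that test was run, against use of other isoforms under KU55933 as a general cause. Isoforms with reads of their own may seldom reach 0 counts in every library, so the criterion weakens that test. Partial shifts in isoform use were not tested. A switch limited to near-identical isoforms stays open, and any difference in preparation or quantification between the groups goes with the treatment.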

How the results depend on the processing

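The GC offsets, the GC slope covariate, the removal of KU55933 1 and 2 together and equal depth were alternatives chosen after seeing the data, and where a value moved the cause was not tested. The direction and call of all 59 named genes held with RLE scaling, and no named gene turned direction with any alternative fixed beforehand. The 4 title genes kept their calls in each of these but the removal of single libraries, which left 3 to 4. Leaving out single libraries gave 1597 to 4348 genes (151 to 1790 higher, 1446 to 2558 lower), 3 to 9 lists and 1446 to 3018 transcripts. An adjusted p of 0.1 gave 5085 genes (2172 higher), no filter 692 higher and the stricter filter 5 lists. DESeq2 gave 1797 higher, limma-voom with sample weights 5231 genes (2248 higher), and an estimated correlation 0 lists (fry passed 3). Fry's 3 lists were the postsynaptic scaffold (adjusted p = 0.0223), voltage-gated sodium and calcium channels (0.0391) and cation-chloride cotransport (0.0453). Of the lists that passed camera, ribosomal proteins (0.31) and choroid plexus (0.377) did not pass fry. With the GC and length offset fry passed 0 lists. Whether replicate numbers pair the libraries stayed open. Vehicle 1, 2 and 4 correlated best with the KU55933 library of the same number (0.294, 0.084 and 0.202), but vehicle 3 with KU55933 2 (0.039 with its own number). As a replicate block they gave 1720 higher genes, 7 lists and 1845 transcripts. With the GC offset there were 231 genes (78 higher, 153 lower), 0 title genes and 10 lists. Reversed log2 changes were Atm -0.061, Slc12a5 0.11, Grik2 -0.055, Wnk2 0.054, Cnih2 0.17, Cacng8 0.51, Grin2c 0.14, Slc32a1 0.21, Nlgn2 0.25 and Sesn2 0.21. With the GC and length offset there were 309 genes (107 higher, 202 lower, unadjusted 2436), 0 title genes and 9 lists. Reversed were Atm -0.083, Slc12a5 0.089, Grik2 -0.070, Neto1 -0.001, Wnk2 0.031, Cnih2 0.20, Cacng8 0.52, Grin2c 0.13, Slc32a1 0.21, Nlgn2 0.22 and Sesn2 0.20. With the GC slope as covariate edgeR gave 0 genes (0 higher, 0 lower, 218 at an unadjusted p under 0.05), 0 title genes and 11 lists, in a fit whose covariate parts the groups without overlap. Reversed were Atm -0.25, Grik3 -0.23, Neto1 -0.21, Neto2 -0.20, Syt9 -0.88, Slc17a6 -0.10, Esr1 -0.97, AW551984 -0.36, Glra3 -1.13, Prkg2 -0.11, Cab39l -0.52, Kcnj13 -3.65, Folr1 -3.06, Prlr -2.28, Slc12a9 0.18, Grin2c 0.25, Gabrg1 -0.12, ribosomal proteins 0.15 and choroid plexus -3.06. Without KU55933 1 and 2, in 6 libraries, there were 1090 genes (105 higher, 985 lower), 2 title genes, 6 lists and 687 transcripts, and the choroid plexus list reversed to -0.12. With the offset as well there were 34 genes (4 higher, 30 lower), 0 title genes and 7 lists. Reversed were Atm -0.10, Slc12a5 0.053, Grik2 -0.024, Neto1 -0.11, H1f10 0.21, Wnk2 0.027, Cnih2 0.17, Cacng8 0.47, Grin2c 0.20, Slc32a1 0.13, Nlgn2 0.090, Sesn2 0.11 and choroid plexus -0.13. The replicate block with the GC and length offset gave 821 genes (362 higher, 459 lower), 1 title gene and 11 lists. Reversed were Atm -0.088, Slc12a5 0.088, Grik2 -0.075, Neto1 -0.010, Wnk2 0.031, Cnih2 0.20, Cacng8 0.53, Grin2c 0.13, Slc32a1 0.21, Nlgn2 0.22 and Sesn2 0.20. The list of title genes never passed camera. With all 8 libraries camera's direction for it turned from down to up with the offsets. The median log2 change was 0.16 without an offset, 0.063 with the GC offset, 0.044 with the GC and length offset and 0.039 with the block as well. With the GC and length offset but without KU55933 1 and 2 the direction stayed down. With the GC slope as covariate the list's median turned to -0.17 and camera's direction stayed down. Unrounded estimates were not run, since the deposited values are whole. In simulated counts at this depth and spread, 46.3% of genes changed 1.5-fold and 74.6% of those changed 2-fold were called, but 9% of transcripts changed 2-fold.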

Other observations

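The GC and length offset was chosen only after the result was seen. Heat shock genes, which encode chaperones, moved both ways in KU55933. Of 15 measured genes 7 rose, 2 fell and 6 did not pass, the same counts as adjusted over the list alone. The rises numbered 2 without vehicle 2, 3 or 4. Hsp90aa1 rose from 1051 to 1338 CPM and the constitutive chaperone gene Hspa8 from 1845 to 2332 CPM (means, n = 4 per group). Their log2 changes were 0.35 ± 0.09 and 0.34 ± 0.11 (SE, adjusted p = 0.0238 and 0.0494 by edgeR's quasi-likelihood test). The stress-inducible genes Hspa1a and Hspa1b fell with log2 changes of -1.17 ± 0.24 and -1.11 ± 0.22 (adjusted p = 0.00945 and 0.00657). The risen genes named had 43% and 51% GC and the fallen ones 58.9% and 58.1%. Camera's adjusted p was 0.177, but 0.00867 without vehicle 1, 0.0444 without KU55933 2 and 0.459 without vehicle 2. With the GC and length offset edgeR called 0 of the 15 and camera's adjusted p was 0.0292, and with an estimated correlation 0.977 without and 0.949 with the offset. Among unfolded protein response genes 4 of 22 rose (Xbp1, Hsp90b1, Dnajb9 and Calr), 2 fell (Atf5 and Chac1) and 16 did not pass, against 5 higher and 2 lower adjusted over the list alone. The rises numbered 13 without vehicle 1, 0 without vehicle 2, 3 or 4, 1 without KU55933 1 and 2 without KU55933 2. The falls numbered 1 without vehicle 2, 3 or 4 or KU55933 1 or 2. Xbp1, a transcription factor of that response, rose with a log2 change of 0.61 ± 0.15 (SE, adjusted p = 0.0193 by edgeR) and had 0.68 with the offset, where edgeR called 0 of the 22 genes. The list's camera adjusted p was 0.0526, and 9.52e-05, 0.0491 and 0.0164 without vehicle 1, vehicle 2 or KU55933 2. It was 0.000387 with the offset, and with an estimated correlation 0.977 without and 0.949 with the offset. These genes were chosen after their values were seen.

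Nuclear genes of oxidative phosphorylation, which encode subunits of the respiratory chain, fell in 24 of 83 cases, rose in 6 and did not pass in 53 (31 lower and 13 higher adjusted over the list alone). The rises numbered 0 without vehicle 2, 3 or 4 and 2 without KU55933 1. The complex III subunit gene Uqcrq had a log2 change of -1.50 ± 0.15 (SE, n = 4 per group, adjusted p = 0.000504 by edgeR) and the complex I subunit gene Ndufs7 one of -1.21 ± 0.14 (adjusted p = 0.00064). With the GC and length offset 13 genes were lower and 0 higher by edgeR, with -1.39 for Uqcrq and -0.49 for Ndufs7. Camera's adjusted p was 0.0835 without and 0.00152 with the offset, and 0.977 and 0.949 with an estimated correlation. The median log2 change was -0.06 without and -0.004 with the offset. With the preset correlation and no offset, camera's adjusted p was 0.0102 and 0.0212 without KU55933 1 or 4 and 0.255 without KU55933 2, where the median was -0.008 (-0.096 without KU55933 1). Dentate granule neuron markers fell in 3 of 15 cases (C1ql2, Pitpnm2 and Plk5, of 59 to 63.4% GC), with the same count adjusted over the list alone, and C1ql2, a synaptic organizer of mossy fibers, had a log2 change of -1.57 ± 0.18 (adjusted p = 0.000669 by edgeR). The list's camera adjusted p was 0.181 (median log2 change -0.12), and 0.0159 and 0.0301 without vehicle 1 or 3, with 5 falls without vehicle 1. It was 0.335 without vehicle 4 (median -0.028) and 0.47 without KU55933 3 (median -0.059). With the offset edgeR called 0 of these 15 and C1ql2 had -0.43, while camera passed (adjusted p = 0.00152, median -0.27), with adjusted p = 0.949 with an estimated correlation. These genes were chosen after their values were seen.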
